A study of Mus musculus with 15 samples.

How the data were processed

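Gene expression was measured by RNA sequencing of total RNA, prepared with the RNeasy micro kit of Qiagen, from sorted mouse liver cells. Per the submitters' processing notes, the deposited values are gene TPM computed with Salmon for the mouse genome build mm10. The version of Salmon is not given in the sources used here. The deposited table held 24493 genes in 15 libraries, and each library was assigned to its group and number by its title. A TPM table keeps no read totals, so the depth of each library and the counting error of each value are unknown. Gene positions were taken from the GENCODE M21 annotation of GRCm38, the same assembly as mm10.

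Genes were kept where the TPM was at least 1 in at least 3 of the 15 libraries, which left 13905. Each library was divided by 1 scale factor, the median over 11603 genes of its ratio to the geometric mean of all libraries. The values analysed were log2(scaled TPM + 1). The deposited values are TPM and not counts, so tests made for counts were not used. Groups were compared with limma 3.58.1 in R 4.3.3, in 1 fit of the 5 groups with a mean-variance trend and 10 residual degrees of freedom. Calls needed a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1 in size. Comparisons were biliary cells with hepatocytes in untreated and in DDC mice, reprogrammed cells with DDC hepatocytes, DDC biliary cells and untreated hepatocytes, DDC with untreated cells within each cell type, and the difference between those DDC responses. These filters, tests, comparisons and gene lists, and the alternatives described below, were set before the data were examined, except where a choice is said to have been made afterwards.

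Gene lists were tested with camera at a preset correlation between genes of 0.01, again with a correlation estimated from the data, and with fry, using statmod 1.5.0. Camera adjusted p-values were adjusted over the lists within a comparison. Of 38 lists, 37 had measured genes, and the list of mitochondrially encoded genes had none. The lists covered hepatocyte functions and zonation, biliary and cilium genes, signalling pathways, matrix, inflammation, stress, proliferation and markers of other liver cells. Biliary genes and hepatocyte genes were defined as the genes called higher in untreated biliary cells and in untreated hepatocytes. The position of a library was the mean of these genes on the way from the mean of DDC hepatocytes to the mean of DDC biliary cells, tested by an exact two-sided permutation of 3 against 3 libraries, whose smallest p is 0.1. Counts expected if 2 sets of calls were independent were the product of their sizes divided by the genes tested.

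Genes named in the text followed a rule. In each comparison it took the 8 called genes with the largest log2 difference in each direction, with at least 10 scaled TPM in the higher group and no overlap between the groups. It added up to 4 called members of each list and a fixed set of marker genes, and for genes beyond both other DDC groups up to 10. Some genes that the rule names are not reported here. Other genes are said to have been chosen after their values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

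The tests were tested on simulated data with known changes. Of 100 genes changed by 2 on the log2 scale, between 92 and 99 were recovered in each of the 7 comparisons of 2 groups, and of 100 changed by 3, between 97 and 100, with 1 to 5 false calls in each. For the difference between the DDC responses, 94 and 99 of 100 were recovered, with 7 false calls. Camera called 20 of 20 lists raised by 1 and 0 of 200 unchanged lists. Simulated genes varied independently of each other, so camera was not tested there on lists of correlated genes. Scale factors were recovered within 2.43%. The numbers in the library titles were checked for pairing through the correlation of deviations from group means across genes. Libraries of the same number correlated at 0.151 to 0.237 between untreated hepatocytes and untreated biliary cells, at 0.136 to 0.449 between DDC hepatocytes and reprogrammed cells and at 0.208 to 0.456 between reprogrammed and DDC biliary cells, all above 0.1. The numbers were therefore taken as pairing these libraries, although the labels do not state that they mark the same animal. For DDC hepatocytes and DDC biliary cells the range was 0.0438 to 0.319, which did not meet that bound.

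Alternatives were TPM as deposited, quantile normalization, pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, only the compared groups in the fit, sample weights, limma without the trend and with robust moderation, the replicate number as a block over all samples or within treatment, the adjusted p alone, the estimated correlation for lists, and leaving out each library in turn. A further pair was chosen after seeing the data: leaving out structural and small RNA genes together with the protein-coding gene Lars2, and leaving out genes higher in untreated hepatocytes from the overlap of the DDC responses. No library was left out of the main analysis.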

Results

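The expression of 24493 genes was measured by RNA sequencing in 15 libraries from sorted mouse liver cells. They formed 5 groups of 3: hepatocytes and biliary cells of untreated mice, and hepatocytes, reprogrammed cells and biliary cells of mice fed DDC, a chow additive that injures bile ducts and hepatocytes. Per the labels, all mice were given AAV-TBG-Cre at 4 weeks of age, a virus that drives Cre from a hepatocyte promoter to label cells, and the DDC mice ate DDC chow from 5 weeks of age for 4 weeks. The series title describes the reprogrammed cells as reprogrammed hepatocytes, and the labels do not state the markers used for sorting. The labels do not state that replicates are separate animals either, so the p-values measure only the spread between these samples. The deposited values are TPM, a relative abundance per transcript, which keep no read total, so the depth of each library is unknown.

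Values below are means of scaled TPM ± SD (n = 3 libraries per group). Log2 differences are between means of log2(scaled TPM + 1), a scale that understates the change of genes with low values, and adjusted p-values are from limma. A gene is called higher, lower, risen or fallen where the adjusted p was under 0.05 and the log2 difference at least 1 in size. In TPM as deposited, the median gene was shifted by 1.11 on the log2 scale between untreated biliary cells and hepatocytes. The shift was 1.06 between the same cell types under DDC and 0.71 between reprogrammed cells and DDC hepatocytes, so the directions below are relative to the median gene after scaling. The number of genes of at least 1 TPM ran from 10231 to 10432 in untreated hepatocytes and from 10751 to 11088 in DDC hepatocytes. It ran from 12553 to 13233 in reprogrammed cells, from 13386 to 13636 in DDC biliary cells and from 12850 to 13097 in untreated biliary cells. The first principal component held 60.4% of the variance and the second 17.1%. Across genes, which are not independent replicates, libraries of reprogrammed cells correlated with DDC biliary libraries at r from 0.902 to 0.959 and with DDC hepatocyte libraries at r from 0.840 to 0.920.

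**Figure D1:**
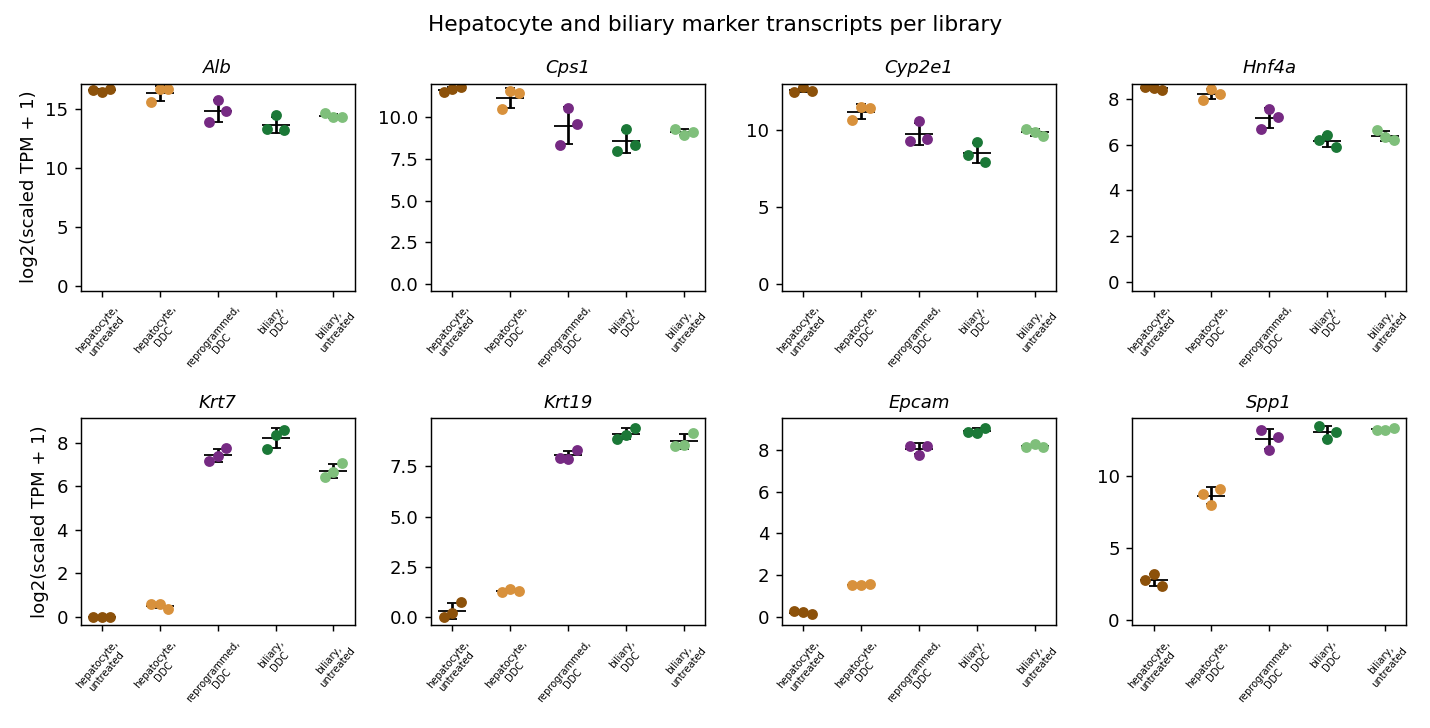
Expression of 4 hepatocyte genes and 4 biliary genes in each library, as log2(scaled TPM + 1), with a point per library (n = 3 per group), the group mean as a line and the SD as a bar. Reprogrammed cells held Alb at 33774 ± 20680 and Krt19 at 264 ± 43.9 scaled TPM, between the DDC hepatocytes and the DDC biliary cells.

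The comparison of untreated biliary cells with untreated hepatocytes gave the reference difference between the 2 cell types. Spp1, the gene for osteopontin (chromosome 5, 104435118 to 104441050, GRCm38, protein-coding), was 6.11 ± 2.04 in hepatocytes and 9866 ± 728 in biliary cells (log2 difference 10.48, adjusted p = 1.5e-10). The bile duct keratin gene Krt19 (chromosome 11, 100140810 to 100148665) was 0.287 ± 0.381 against 436 ± 118 (log2 difference 8.42). Epcam, which codes for an epithelial adhesion molecule (chromosome 17, 87635979 to 87651129), was 0.162 ± 0.0673 against 291 ± 13.1 (log2 difference 7.97). Krt7, the other keratin of bile ducts (chromosome 15, 101411043 to 101430313), was listed at 0 in each hepatocyte library and at 83.8, 99.5 and 133 in the biliary libraries. The transcription factor gene Sox9 was also higher in biliary cells, at 121 ± 11.2 against 2.76 ± 0.253. Albumin mRNA (Alb, chromosome 5, 90460897 to 90476602) was 99160 ± 6949 in hepatocytes and 22303 ± 2988 in biliary cells (log2 difference -2.16, adjusted p = 0.00625). Of 13905 genes tested, 3005 were higher and 2161 lower in biliary cells, or 7350 higher and 470 lower in TPM as deposited.

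Genes of hepatocyte functions were lower in biliary cells as groups. They included 20 of 20 genes of plasma proteins (camera adjusted p = 5.6e-07, adjusted p = 0.285 with an estimated correlation) and 20 of 20 genes of the urea cycle and amino acid breakdown (2.18e-06, adjusted p = 0.274 with an estimated correlation). Further such groups were the xenobiotic P450 enzymes (19 of 19 lower, camera adjusted p = 9.48e-06) and bile acid synthesis and transport (16 lower and 1 higher of 18, 2.36e-05), both with adjusted p = 0.262 with an estimated correlation. Fatty acid oxidation and ketogenesis was lower too (17 of 20 lower, 5.6e-07), as was gluconeogenesis (13 lower and 1 higher of 15, 0.00016), again with adjusted p = 0.262 with an estimated correlation for both. The same held for heme synthesis and degradation (10 of 16 lower, 4.79e-06), pericentral genes (13 of 18, 7.85e-05), periportal genes (17 of 18, 2.43e-05) and hepatocyte transcription factors (11 lower and 4 higher of 17, 0.00504). These 4 lists had adjusted p = 0.262 with an estimated correlation, and for all of the lists of hepatocyte functions above the counts adjusted over the list alone were the same. Examples were Cyp2e1, a P450 enzyme of pericentral hepatocytes (6288 ± 667 against 942 ± 142), and Cps1, the first enzyme of the urea cycle (3278 ± 352 against 558 ± 62.4). Hnf4a, a transcription factor of hepatocyte identity, was 356 ± 18.9 against 84.2 ± 13.8. Hepatocyte transcripts stayed high in the biliary libraries. Over 76 genes of the hepatocyte lists, the deposited TPM of untreated biliary cells was a median of 42.7% of that of untreated hepatocytes (quartiles 40.3% and 47.3%), and no gene lay below 32.3%.

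**Figure D2:**
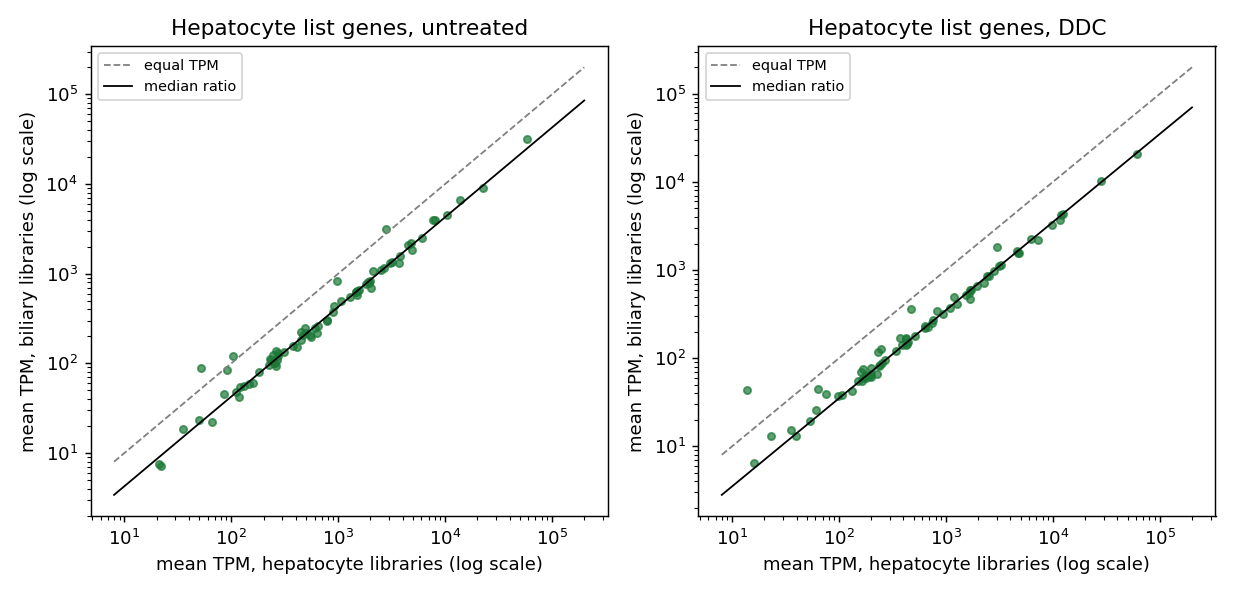
Mean deposited TPM of hepatocyte list genes in biliary libraries against hepatocyte libraries, on log axes, with a point per gene, for untreated mice and for mice fed DDC; the dashed line marks equal values and the solid line the median ratio. The median ratio was 42.7% in untreated mice and 35.1% under DDC.

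Biliary cells had 23 of 24 biliary epithelial markers higher (camera adjusted p = 3.3e-12) and 16 of 19 genes of the primary cilium (2.37e-05), each with adjusted p = 0.262 with an estimated correlation. Also higher were 14 of 21 YAP/TAZ targets beside 1 that was lower (4.05e-05), 8 of 14 Notch pathway genes (0.000427) and 12 of 21 TGF-beta pathway genes (0.000431), all with adjusted p = 0.262 with an estimated correlation. Fetal liver and progenitor genes (10 of 14 higher, 0.00257) and DNA and histone methylation enzymes (10 of 22, 0.00388) were also called higher. Their adjusted p = 0.262 with an estimated correlation, and for these 7 lists the counts adjusted over the list alone were the same. Among their members, the YAP/TAZ target Ctgf (annotated as Ccn2, chromosome 10, 24595442 to 24598683) was 158 ± 18.9 against 0.121 ± 0.0759. The Notch target Hes1 was 224 ± 83.3 against 2.96 ± 0.473 and the cilium gene Pkhd1, which codes for fibrocystin, 79.1 ± 7.49 against 1.89 ± 0.426. Basement membrane genes (13 higher and 2 lower of 18, 0.000358) had an adjusted p = 0.274 with an estimated correlation, and immediate early genes that respond to cell dissociation (14 of 20 higher, 0.00111) an adjusted p = 0.277 with an estimated correlation. Inflammatory chemokines and NF-kB targets were also called (8 of 19 higher, 0.0355, with adjusted p = 0.437 with an estimated correlation), as were MHC class II genes (6 of 7, 0.00837, with adjusted p = 0.333 with an estimated correlation). Cholesterol synthesis (15 of 21 lower, 0.000183), NRF2 targets (14 lower and 4 higher of 21, 0.0121) and the acute phase response (15 lower and 3 higher of 19, 0.0016) were called lower, with adjusted p = 0.454, 0.414 and 0.285 with an estimated correlation. The counts of these 7 lists adjusted over the list alone were the same.

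The comparison of reprogrammed cells with hepatocytes of the same treatment asked what separated the reprogrammed cells from their hepatocyte neighbours. Krt19 was 1.49 ± 0.126 in DDC hepatocytes and 264 ± 43.9 in reprogrammed cells (log2 difference 6.72, adjusted p = 4.42e-10). Krt7 was 0.428 ± 0.117 against 174 ± 37.1 (log2 difference 6.92) and Epcam 1.91 ± 0.0392 against 265 ± 45.9 (log2 difference 6.50). Mmp7, a matrix protease gene, was 2.16 ± 0.736 against 413 ± 31.7 (log2 difference 7.06). Sox9 rose from 9.65 ± 3.58 to 67.2 ± 14.0 and Spp1 from 417 ± 155 to 6666 ± 3012. Cd24a, which codes for a surface glycoprotein (chromosome 10, 43578284 to 43584265), rose from 7.56 ± 2.05 to 403 ± 64.0. Cps1 fell from 2447 ± 878 to 869.7 ± 585 (log2 difference -1.67, adjusted p = 0.0122) and Hnf4a from 299.9 ± 45.4 to 148 ± 44.0 (log2 difference -1.05). Alb did not pass the test, at 87653 ± 32270 against 33774 ± 20680 (log2 difference -1.49, adjusted p = 0.0566). That test does not use the pairing by number. By number, Alb was 50450, 104400 and 108100 in the DDC hepatocyte libraries and 15210, 56070 and 30040 in the reprogrammed libraries. The transcription factor gene Cebpa passed the adjusted p with a log2 difference of -0.91, short of 1 in size. In all, 1916 genes were higher and 791 lower in reprogrammed cells, or 4240 and 9 in TPM as deposited.

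Reprogrammed cells had 22 of 24 biliary markers higher than DDC hepatocytes (23 adjusted over the list alone, camera adjusted p = 4.97e-16, adjusted p = 0.198 with an estimated correlation). They also had 16 of 21 YAP/TAZ targets higher and 1 lower (1.89e-06, adjusted p = 0.198 with an estimated correlation), with Ctgf at 270.1 ± 33.3 against 10.9 ± 5.52 and Ankrd1 at 73.9 ± 14.3 against 1.17 ± 0.512. The same direction was called for the TGF-beta pathway (10 of 21 higher, 1.13e-05), basement membrane (13 of 18, 3.38e-06) and inflammatory chemokines and NF-kB targets (13 of 19, 3.38e-06), all with adjusted p = 0.198 with an estimated correlation. It was also called for the Notch pathway (5 of 14, 0.000779) and fetal liver genes (7 of 14, 0.00181). Both had adjusted p = 0.198 with an estimated correlation, and apart from the biliary markers the counts of these 7 lists adjusted over the list alone were the same. Examples were Thbs1, the gene for thrombospondin 1 (39.7 ± 0.770 against 0.706 ± 0.312), the chemokine gene Cxcl5 (82.6 ± 32.7 against 0.344 ± 0.0575), the Notch ligand gene Jag1 (47.6 ± 9.05 against 3.86 ± 0.893) and Cd44 (127 ± 25.9 against 5.21 ± 3.36). Genes of the primary cilium (10 of 19 higher, 3.85e-05) had an adjusted p = 0.25 with an estimated correlation, and fibrillar collagen and matrix genes (6 of 13, 0.00245) an adjusted p = 0.329 with an estimated correlation. Targets of p53 and senescence genes were called at 0.0478 (adjusted p = 0.437 with an estimated correlation). Higher were 5 of 17, among them the cell cycle inhibitor gene Cdkn2a (5.22 ± 1.60 against 0.0708 ± 0.123). The counts of these 3 lists adjusted over the list alone were the same.

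On the hepatocyte side, 18 of 20 plasma protein genes were lower in reprogrammed cells (19 adjusted over the list alone, camera adjusted p = 1.89e-06, adjusted p = 0.312 with an estimated correlation). The urea cycle and amino acid list had 13 of 20 lower (17 adjusted over the list alone, 5.66e-06, adjusted p = 0.3 with an estimated correlation), and the P450 enzymes 11 of 19 (12 adjusted over the list alone, 1.94e-05, adjusted p = 0.297 with an estimated correlation). Bile acid genes had 10 of 18 lower (10 adjusted over the list alone, 1.94e-05, adjusted p = 0.262 with an estimated correlation). Cholesterol synthesis had 10 of 21 lower (10 adjusted over the list alone, 1.94e-05, adjusted p = 0.404 with an estimated correlation). The bile salt export pump gene Abcb11 fell from 249 ± 9.93 to 84.1 ± 27.4 and Apoc3, an apolipoprotein gene, from 10509 ± 4241 to 3724 ± 1710. NRF2 targets went both ways, with 3 higher and 6 lower of 21, counts that were the same adjusted over the list alone (camera adjusted p = 0.0432, adjusted p = 0.446 with an estimated correlation). That list was called lower, and under quantile normalization its value was 0.0113 with the opposite sign and no call. Among genes of at least 10 scaled TPM, the largest falls included Rn45s, the ribosomal RNA precursor, at 3644 ± 1115 against 686 ± 127, and the protein-coding gene Lars2 at 1170.5 ± 424 against 212 ± 26.9. Over 75 hepatocyte list genes, the deposited TPM of reprogrammed cells was a median of 66.6% of that of DDC hepatocytes, and 48.0%, 92.3% and 62.1% in libraries 1, 2 and 3.

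The comparison of reprogrammed cells with biliary cells of the same treatment asked how close they came to biliary cells. The difference lay mainly in hepatocyte genes. In reprogrammed cells 384 genes were higher, of which 361 (94%) were genes higher in untreated hepatocytes than in untreated biliary cells, and 106 were lower, of which 79 were biliary genes. Plasma protein genes had 15 of 20 higher (17 adjusted over the list alone, camera adjusted p = 5.3e-11, adjusted p = 0.263 with an estimated correlation). Examples were Vtn, which codes for vitronectin (1293 ± 235 against 447 ± 167), and Ahsg, which codes for fetuin A (6121 ± 1976 against 2170.2 ± 735). Urea cycle genes had 7 of 20 (11 adjusted over the list alone, 1.09e-08), gluconeogenesis 8 of 15 (11 adjusted over the list alone, 5.47e-07) and acute phase genes 7 of 19 (8 adjusted over the list alone, 1.43e-05), all with adjusted p = 0.263 with an estimated correlation. Of the biliary markers, 4 of 24 were lower (5 adjusted over the list alone, 7.26e-09, adjusted p = 0.263 with an estimated correlation), namely Krt19 (264 ± 43.9 against 559.9 ± 106, log2 difference -1.08), Muc1, Sctr and Grhl2. Epcam, at 265 ± 45.9 against 479 ± 46.4, passed the adjusted p (0.00295) with a log2 difference of -0.86, short of 1 in size. Sox9 (67.2 ± 14.0 against 99.1 ± 5.08) and Spp1 (6666 ± 3012 against 8676 ± 2538) did not pass it. Cdh2, the gene for N-cadherin, was higher in reprogrammed cells (adjusted p = 0.000143, log2 difference 1.19), and so was the fetal liver gene Afp (4.81 ± 1.05 against 1.48 ± 0.720). The mean of Afp was higher still in DDC hepatocytes, as given below, so its level does not set reprogrammed cells apart from them. Nor was Cdh2 called higher in reprogrammed cells than in DDC hepatocytes. Of 12 mesenchymal and EMT genes, 0 were higher than in both other DDC groups. The split turned over in TPM as deposited, to 120 higher and 576 lower, and the count fell to 3 when only these 6 libraries were in the fit. Without DDC biliary library 3 the count was 102, without reprogrammed library 2 it was 137, and without reprogrammed library 1 it was 833. The main fit shared 1 spread per gene over all 5 groups. Replicates correlated at r from 0.974 to 0.978 in untreated hepatocytes and from 0.967 to 0.975 in untreated biliary cells. In DDC hepatocytes, reprogrammed cells and DDC biliary cells r ran from 0.944 to 0.967, 0.934 to 0.963 and 0.938 to 0.955. The p-values of the main fit can therefore understate the spread of the DDC libraries.

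The 3005 genes higher in untreated biliary cells and the 2161 genes higher in untreated hepatocytes were then followed into the DDC groups, which share no library with the untreated ones. Of the biliary genes, 1590 (52.9%) were higher in reprogrammed cells than in DDC hepatocytes, where 414 would be called in both comparisons if they were independent, 1 was lower, and 2908 (96.8%) had the same sign. Of the hepatocyte genes, 763 (35.3%) were lower in reprogrammed cells, against 123 if independent, 6 were higher, and 2106 (97.5%) had the same sign. The median log2 difference from DDC hepatocytes was 1.08 for biliary genes in reprogrammed cells and 1.49 in DDC biliary cells, and -0.87 and -1.48 for hepatocyte genes. In TPM as deposited the first count was 3844 and the second 1. There both gene sets were defined anew, with the sizes given above for deposited TPM, so these counts are not shares of 3005 and 2161. Without reprogrammed library 1 the second count was 497. On the way from DDC hepatocytes to DDC biliary cells, reprogrammed libraries stood at 77.1 ± 12.1% for the mean of biliary genes (87.6%, 63.9% and 79.8%) and at 57.3 ± 15.7% for the mean of hepatocyte genes (71.2%, 40.3% and 60.5%). Each reprogrammed library lay between the libraries of the other two DDC groups on both measures (two-sided exact permutation p = 0.1 against each group, the smallest that 3 against 3 allow). In TPM as deposited the hepatocyte gene position was 40.0%. Untreated biliary cells stood at 75.5 ± 8.3% for hepatocyte genes on the same measure.

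**Figure D3:**
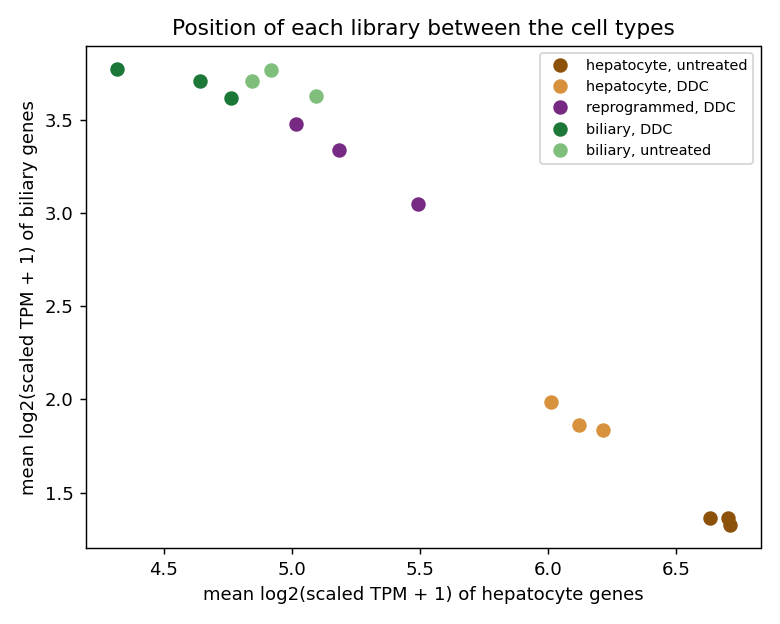
Mean log2(scaled TPM + 1) of the biliary genes (vertical) against that of the hepatocyte genes (horizontal), with a point per library, coloured by group. Reprogrammed libraries had a mean of 3.29 for biliary genes and 5.23 for hepatocyte genes, between DDC hepatocytes (1.89 and 6.11) and DDC biliary cells (3.70 and 4.57).

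Few genes set the reprogrammed cells apart from both other DDC groups. The transcription factor gene Tbx1 (chromosome 16, 18580979 to 18590671) was 14.4 ± 7.71 in reprogrammed cells, 0.914 ± 0.795 in DDC hepatocytes and 0.787 ± 0.549 in DDC biliary cells. Gpc3, the gene for glypican 3 (chromosome X, 52272426 to 52613950), was 11.8 ± 5.16, 4.23 ± 2.41 and 2.97 ± 0.182, and the sodium channel gene Scn7a 10.6 ± 5.26, 0.256 ± 0.257 and 3.32 ± 1.34. In all, 8 genes were higher than in both groups, with Mir25 as the fourth that the naming rule picked, and 3 were lower, Rn45s, Lars2 and Snora34. Snora34 and the higher genes Mir7024, Ms4a4d, Msc and Col12a1 fell outside the rule and were chosen after their values were seen. Both comparisons share the reprogrammed libraries, while independent lists of the sizes called would share 52.9 and 6.03 genes. In 20 simulations 0 such genes were called, but there no group differed from any other. The simulations therefore do not tell how many such genes chance gives where DDC hepatocytes and DDC biliary cells differ. The higher count was 3 without reprogrammed library 3 or DDC biliary library 3, 4 without DDC biliary library 1 or 2, 5 without reprogrammed library 1, and 17 with sample weights. With only the compared groups in the limma fit both counts were 0, against 8 higher and 6 lower genes at unadjusted p under 0.05. The higher count was 4 with a pseudocount of 0.1, 3 with a pseudocount of 5 and 5 with a filter of 5 TPM, and the lower count was 12 with sample weights.

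DDC in hepatocytes was followed by comparing DDC hepatocytes with untreated hepatocytes. The genes that fell most were members of the major urinary protein family. The sum of its 21 members, which are near-identical paralogs and therefore uncertain one by one, was 195937 ± 53955 in untreated and 3542 ± 4743 in DDC hepatocytes. These were 11.4 ± 2.78% and 0.269 ± 0.374% of the deposited TPM. The DDC libraries held 9003, 442 and 1182, so that the mean was 812 without library 1. Most of the remainder was Mup20, which did not pass the test (11277 ± 3748 and 3456 ± 4682, adjusted p = 0.104) and was chosen after its values were seen. Without Mup20 the sum was 86.4 ± 61.7 in DDC hepatocytes. Mup10 (chromosome 4, 60578260 to 60582199) was 73793 ± 13260 and 11.5 ± 6.03. Mup19 (chromosome 4, 61778324 to 61782269) was at 14600, 11500 and 19000 in the untreated libraries and listed at 0 in each DDC library. Cd63, which codes for a lysosomal and exosomal membrane protein (chromosome 10, 128900989 to 128912822), rose from 1.41 ± 0.435 to 497 ± 252 (log2 difference 7.59, adjusted p = 3.93e-09). Lcn2, the gene for lipocalin 2, rose from 32.5 ± 29.5 to 1855 ± 402 and the keratin gene Krt8 from 406 ± 81.5 to 2075 ± 761. The organic anion transporter gene Slco1a1 fell from 439 ± 49.0 to 0.143 ± 0.172 (log2 difference -8.59, adjusted p = 2.67e-12). Cyp8b1, an enzyme of bile acid synthesis, fell from 387 ± 162 to 22.9 ± 10.4. Fech, the enzyme that completes heme, did not pass the test at 117 ± 4.13 and 111 ± 6.25 (adjusted p = 0.704), nor did Alb (99160 ± 6949 and 87653 ± 32270). Of the genes tested, 914 rose and 615 fell, or 1036 and 360 in TPM as deposited. Of the 914, 567 were biliary genes, and of the 615, 390 (63.4%) were hepatocyte genes. Among all 13905 genes tested, 3005 were biliary and 2161 (15.5%) hepatocyte genes. Both sets were defined with the same untreated hepatocyte libraries that serve as the control here, which favours such counts.

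Fetal liver and progenitor genes had 12 of 14 higher under DDC (camera adjusted p = 5.63e-10, adjusted p = 0.0525 with an estimated correlation). Among them were Sox4 (0.0444 ± 0.0391 to 8.09 ± 2.70), Prom1 (0.0648 ± 0.0919 to 23.7 ± 14.0) and Afp (0.970 ± 0.526 to 6.51 ± 2.43). Inflammatory chemokines and NF-kB targets had 11 of 19 higher (12 adjusted over the list alone, 1.11e-06, adjusted p = 0.333 with an estimated correlation). The monocyte chemokine gene Ccl2 (chromosome 11, 82035571 to 82037453) was 0.816 ± 1.41 and 74.2 ± 38.2. Biliary markers had 10 of 24 higher (4.6e-07, adjusted p = 0.335 with an estimated correlation), with Spp1 at 6.11 ± 2.04 and 417 ± 155 and Epcam at 0.162 ± 0.0673 and 1.91 ± 0.0392. YAP/TAZ targets had 9 of 21 higher (10 adjusted over the list alone, 6.75e-05, adjusted p = 0.335 with an estimated correlation), with Ctgf at 0.121 ± 0.0759 and 10.9 ± 5.52. Mesenchymal and EMT genes had 6 of 12 higher (0.00413, adjusted p = 0.335 with an estimated correlation), such as Vim, which codes for vimentin (0.623 ± 0.518 to 10.5 ± 4.65). NRF2 targets (8 higher and 1 lower of 21, 0.00676), the acute phase response (8 higher and 2 lower of 19, 0.0201) and basement membrane (7 higher and 1 lower of 18, 0.00413) were called higher, all with adjusted p = 0.526 with an estimated correlation. So were the Notch pathway (2 of 14, 0.0397) and fibrillar collagen (3 of 13, 0.0119), both with adjusted p = 0.526 with an estimated correlation. Interferon response genes were called lower (8 of 20, and 10 adjusted over the list alone, 0.000655, adjusted p = 0.526 with an estimated correlation). Also lower were the urea cycle list (5 of 20, 0.00107) and fatty acid oxidation (4 of 20, 0.00066), with Fabp1, the liver fatty acid binding protein gene, at 21153 ± 1033 and 1968 ± 2273. These last 2 lists had adjusted p = 0.526 with an estimated correlation. Except where a count is given, the counts adjusted over the list alone were the same.

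The comparison of DDC biliary cells with untreated biliary cells asked what DDC changed in biliary cells. Ccl2 rose from 0.730 ± 0.322 to 344 ± 55.8 (log2 difference 7.64, adjusted p = 4.71e-07) and the neutrophil chemokine gene Cxcl5 (chromosome 5, 90759360 to 90761624) from 1.62 ± 0.977 to 200.3 ± 69.4. Cd44, which codes for a hyaluronan receptor, rose from 3.23 ± 0.591 to 216 ± 32.1 and Mmp7 from 24.1 ± 5.31 to 964 ± 97.2. The chloride channel gene Cftr rose from 9.64 ± 1.59 to 48.6 ± 19.9 and Krt7 from 106 ± 25.2 to 307 ± 91.4 (log2 difference 1.51), while Krt19, Sox9 and Spp1 did not pass the test. Inflammatory chemokines and NF-kB targets had 17 of 19 higher (camera adjusted p = 3.22e-16, adjusted p = 0.0697 with an estimated correlation). The TGF-beta pathway had 11 higher and 2 lower of 21 (1.46e-05, adjusted p = 0.361 with an estimated correlation), with Ltbp2 at 0.288 ± 0.172 and 49.2 ± 14.8. Targets of p53 and senescence genes had 7 higher and 1 lower of 17 (8.58e-05, adjusted p = 0.369 with an estimated correlation). Cdkn2a was 0.0657 ± 0.0702 and 10.3 ± 3.21 and Cdkn2b 1.20 ± 0.343 and 22.7 ± 3.99. Immediate early genes were lower (10 lower and 2 higher of 20, 0.000294, adjusted p = 0.389 with an estimated correlation), for example Atf3 (352 ± 252 to 66.7 ± 26.5). Interferon response genes were also lower (7 of 20, and 8 adjusted over the list alone, 8.58e-05, adjusted p = 0.508 with an estimated correlation). Apart from the interferon list, these counts adjusted over the list alone were the same. In total 800 genes rose and 655 fell. Of the 655, 274 (41.8%) were hepatocyte genes, such as the Mup family with a sum of 32751 ± 13064 in untreated and 689 ± 1009 in DDC biliary cells, and 246 were biliary genes. The DDC biliary libraries held 1854, 103 and 110 of that sum, or a mean of 106 without library 1. Hepatocyte and biliary genes made up 2161 and 3005 of the 13905 genes tested, and were defined with the same untreated biliary libraries.

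**Figure D4:**
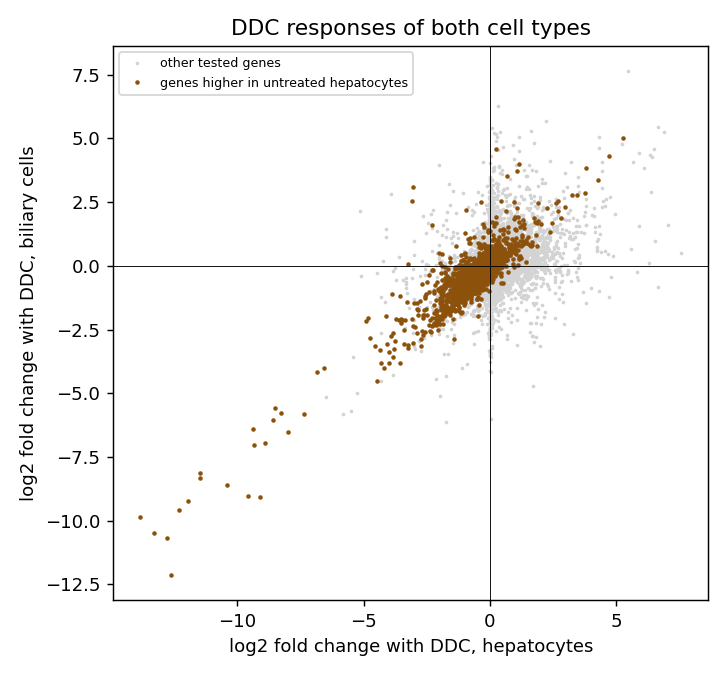
Log2 difference between DDC and untreated cells in biliary cells (vertical) against hepatocytes (horizontal), with a point per tested gene, and in brown the genes higher in untreated hepatocytes than in untreated biliary cells. Across 13905 genes, Pearson's r was 0.575.

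Set side by side, the DDC responses of the 2 cell types shared 235 genes that rose, against 52.6 if independent, and 292 that fell, against 29, with 23 and 3 genes called in opposite directions. The 2 responses share no library, but libraries of the same number deviated together between untreated hepatocytes and untreated biliary cells. Between DDC hepatocytes and DDC biliary cells they did so on average (mean r = 0.227, from 0.0438 to 0.319). The mean of -0.113 for other numbers is no separate evidence, since deviations from a group mean cancel within the group. The counts for independent responses do not take these shared deviations into account. Lcn2 rose in both, to 1855 ± 402 in hepatocytes and 1978 ± 745 in biliary cells, as did Ccl2, and Slco1a1 and G6pc, the glucose-6-phosphatase gene, fell in both (1230.3 ± 189 to 210.3 ± 109 and 208 ± 36.8 to 34.8 ± 22.0). Of the 292 genes that fell in both, 228 (78.1%) were hepatocyte genes, and of the 235 that rose in both, 29 were. Without the genes higher in untreated hepatocytes the shared counts were 206 and 64, against 53.3 and 7.30 if independent. Leaving those genes out does not remove genes that only DDC raised in hepatocytes. RNA of hepatocytes in the biliary libraries could thus still add to the shared rises. The response itself differed between the cell types for 1166 genes in a test of the interaction. Cd63 rose by 7.59 in hepatocytes, while its log2 difference in biliary cells was 0.51, and Spp1 rose by 5.84 in hepatocytes against a difference of -0.22 in biliary cells. Cxcl5 rose by 6.26 in biliary cells and differed by 0.34 in hepatocytes, and Serpine2, the gene for protease nexin 1, fell by 3.04 in hepatocytes and rose by 3.09 in biliary cells. As lists, fetal liver genes (6 more positive in hepatocytes and 1 in biliary cells of 14, camera adjusted p = 3.05e-05), immediate early genes (12 and 1 of 20, 3.05e-05) and biliary markers (10 and 4 of 24, 0.00301) responded more positively in hepatocytes, with adjusted p = 0.458, 0.548 and 0.988 with an estimated correlation. Inflammatory chemokines (1 and 7 of 19, 1.4e-05) and p53 targets (1 and 3 of 17, 6.21e-05) responded more positively in biliary cells, both with adjusted p = 0.548 with an estimated correlation. Adjusted over the list alone, the counts were 7 and 1, 12 and 2, 11 and 5, 1 and 9, and 1 and 6.

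The comparison of reprogrammed cells with untreated hepatocytes asked how far they stood from cells without DDC. Spp1 was 6666 ± 3012 against 6.11 ± 2.04 (log2 difference 9.80, adjusted p = 4.26e-10). Cd24a was 403 ± 64.0 against 0.111 ± 0.103 and Ctgf 270.1 ± 33.3 against 0.121 ± 0.0759. Hnf4a was 148 ± 44.0 against 356 ± 18.9 and Cyp2e1 949 ± 500.1 against 6288 ± 667. Fetal liver genes had 13 of 14 higher (camera adjusted p = 2.02e-06), inflammatory genes 17 of 19 (4.15e-07), TGF-beta pathway genes 16 of 21 (8.28e-07) and biliary markers 23 of 24 (2.13e-13), all with adjusted p = 0.146 with an estimated correlation. The urea cycle list had 20 of 20 lower (8.28e-07, adjusted p = 0.282 with an estimated correlation). In total 2871 genes were higher and 1719 lower, or 6356 and 446 in TPM as deposited. Between the DDC biliary cells and DDC hepatocytes, biliary markers had 24 of 24 higher (6.78e-12) and plasma protein genes 20 of 20 lower (2.72e-08), with adjusted p = 0.214 and 0.233 with an estimated correlation. Krt19 was 559.9 ± 106 against 1.49 ± 0.126 and Alb 14083 ± 7373 against 87653 ± 32270 (log2 difference -2.68). The counts of these lists adjusted over the list alone were the same. That comparison had 2835 genes higher and 1978 lower, or 7142 and 645 in TPM as deposited and 2038 and 2189 under quantile normalization. Over 75 hepatocyte list genes, the deposited TPM of DDC biliary cells was a median of 35.1% of that of DDC hepatocytes, and none lay below 28.3%.

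The leukocyte gene Ptprc was 0.531 ± 0.199 in reprogrammed cells, 0.340 ± 0.176 in DDC hepatocytes and 0.816 ± 0.307 in DDC biliary cells, and the macrophage gene Adgre1 0.712 ± 0.289, 0.325 ± 0.132 and 1.02 ± 0.835. Between reprogrammed cells and DDC hepatocytes, 3 of 17 macrophage markers were higher (2 adjusted over the list alone, camera adjusted p = 0.161), as were 1 of 14 endothelial markers (0.501). Also higher were 3 of 15 stellate cell and fibroblast markers (2 adjusted over the list alone, 0.106) and 1 of 6 lymphocyte and granulocyte markers (0.198). Under DDC, lymphocyte and granulocyte markers rose as a list in hepatocytes (4 of 6 higher, 5 adjusted over the list alone, camera adjusted p = 0.00413, adjusted p = 0.333 with an estimated correlation) and in biliary cells (4 of 6, 4 adjusted over the list alone, 0.000294, adjusted p = 0.194 with an estimated correlation). Coro1a, a leukocyte gene of the actin cytoskeleton, rose from 0.232 ± 0.163 to 2.08 ± 0.663 in hepatocytes and from 0.385 ± 0.0537 to 3.55 ± 0.850 in biliary cells. Macrophage markers were not called as a list by camera, with 3 higher and 1 lower of 17 in hepatocytes (0.532) and 5 and 1 in biliary cells (0.448). Lyz2, the lysozyme gene of macrophages and neutrophils, rose from 4.03 ± 2.41 to 18.8 ± 2.94 and from 10.4 ± 3.21 to 53.9 ± 26.6, and Tyrobp from 2.38 ± 0.692 to 6.22 ± 1.22 and from 3.97 ± 1.71 to 14.4 ± 4.70. These rises accompanied those of the inflammatory chemokine list. Between reprogrammed cells and DDC hepatocytes, mesothelial markers had 2 of 3 higher (0.0315, adjusted p = 0.198 with an estimated correlation), while 1 of 4 erythroid markers was lower (0.346). Rgs5, a marker of pericytes and stellate cells, was 343 ± 73.8 in reprogrammed cells, 465 ± 89.7 in DDC biliary cells, 106 ± 2.34 in untreated biliary cells and 0.158 ± 0.151 in untreated hepatocytes. Msln, the mesothelin gene, was 51.0 ± 13.4 in reprogrammed cells and 118 ± 31.3 in DDC biliary cells. MHC class II genes had 4 of 7 higher in reprogrammed cells (0.0305, adjusted p = 0.424 with an estimated correlation) and DNA and histone methylation enzymes 1 of 22 (0.0206, adjusted p = 0.301 with an estimated correlation). Proliferation genes were not called in that comparison (1 of 26 higher, 0.682), and Mki67 was 9.61 ± 4.92 in reprogrammed cells, 7.34 ± 7.49 in DDC hepatocytes and 11.5 ± 2.12 in DDC biliary cells. Among the reference genes, Gapdh was 1052 ± 119 in DDC biliary cells against 2553 ± 216 in DDC hepatocytes (log2 difference -1.28), a direction that turned to 0.03 under quantile normalization. Reference genes as a list had 1 higher and 1 lower of 14 between reprogrammed cells and DDC hepatocytes (camera adjusted p = 0.135), and keratin and Mallory-Denk body genes 5 higher (6 adjusted over the list alone) and 1 lower of 14 (0.323). Krt8, a keratin of both epithelia, was 1825 ± 427 in reprogrammed cells and 1630.4 ± 119 in DDC biliary cells.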

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

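The tests of hepatocyte RNA in the biliary libraries, the splits that keep same-numbered libraries together, the centred version of the mixture test and the bound for genes beyond both other DDC groups were chosen only after the results were seen, as was the stricter reading of the mixture test.

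The DDC response differed between hepatocytes and biliary cells for 1166 genes by a test of the interaction, 681 with a more positive response in hepatocytes and 485 in biliary cells. The difference of the responses (log2) was 7.51 for Snord95, 7.08 for Cd63, 6.21 for Mfge8, 6.07 for Msmp, 6.07 for Spp1, 5.96 for Id1, 5.55 for Anxa2 and 5.46 for S100a11. For Msmp the responses were 0.06 in hepatocytes and -6.01 in biliary cells, and of the 681 genes 316 were called only in hepatocytes and 175 only in biliary cells. On the biliary side the difference was -7.32 for Snora43, -6.14 for Serpine2, -5.92 for Cxcl5, -5.33 for Ctse, -4.90 for Plau, -4.83 for Ltbp2 and -4.76 for Gabrp. Among the fixed markers, Sox9 (1.72), Cd24a (1.66) and Ctgf (2.24) had a more positive response in hepatocytes. Of 100 drawn splits of cell type within treatment, 11 gave as many genes, the highest other 5947, so chance was not excluded for the count. The splits with several times the real count put the difference between the cell types into the interaction, a structure of the samples and not of the response.

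Hepatocyte transcripts were abundant in the biliary libraries. If RNA of hepatocytes were the source, all abundant hepatocyte genes would keep a similar ratio, and 0 of 76 list genes in untreated biliary cells had a ratio below 0.5 of the median ratio, a percentage of 0. Among 119 genes of at least 1000 TPM in untreated hepatocytes the lowest ratio was 34.3% against a median of 44.2%, and Alb made up 2.991% to 3.426% of the TPM in untreated biliary libraries. If the biliary cells themselves expressed these genes, ratios and DDC responses could differ from gene to gene. The ratios had quartiles of 40.3% and 47.3%, and over 77 list genes the DDC responses of both cell types correlated at r = 0.955. Their median absolute difference was 0.192, and 2 were called in the interaction. These values argue against own expression as the main source for the list genes as a set. Over 2161 hepatocyte genes the median absolute difference was 0.226, and over the 445 called in DDC hepatocytes 0.502. Of those 445, 63 were called in the interaction, which leaves own expression of single genes open. RNA of hepatocytes may therefore account for part of the hepatocyte signal in biliary and reprogrammed libraries. It may also account for the falls of hepatocyte genes shared between the cell types, and in part for shared rises of genes that DDC raised in hepatocytes. The labels name no sort marker or gate that would remove such RNA.

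Reprogrammed libraries lay between hepatocyte and biliary libraries, as a mixture of both cells might. The mixture of the DDC hepatocyte and DDC biliary library of the same number had fitted hepatocyte shares of 32.1%, 64.2% and 54.2%. Against it 2 genes differed, Snord66 and Mir6936, chosen after their values were seen. Simulations of independent noise, with no libraries mixed, gave up to 2. They do not tell how many genes true mixtures would give. The test of the real libraries had 3403 of 13905 genes at unadjusted p under 0.05, against 695 by chance. The centred version gave 6 genes and 2314. In the first version, planted shifts of 1 and 2 were recovered for 49.6% and 97.4% of genes. The 6 genes beyond both other DDC groups, counted without Lars2 and the structural and small RNAs, do not decide either, since the count of all 8 higher genes ranged from 0 to 17 over the alternatives. A mixture and cells of an intermediate state cannot be told apart here.

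Of Rn45s, Lars2 and Mir6236, features that can collect ribosomal RNA reads, the first 2 were lower in reprogrammed libraries than in both other DDC groups, while Mir6236 was called lower than in DDC hepatocytes only (adjusted p = 0.000859, and 0.139 against DDC biliary cells). After removing group means, Rn45s and Mir6236 correlated over 15 libraries (r = 0.755, rho = 0.714, permutation p = 0.00061 and 0.0037, r = 0.643 without the 2 farthest libraries, and 0.00061 and 0.0037 adjusted over 3 relations). Mir6236 made up 2.94 ± 0.37% of the TPM in reprogrammed, 10.6 ± 4.37% in DDC hepatocyte and 7.81 ± 0.791% in DDC biliary libraries, against 3.39 ± 0.536% in untreated hepatocyte and 2.12 ± 0.148% in untreated biliary libraries, so the reprogrammed libraries were close to the untreated ones and the other two DDC groups were high. A difference between libraries in the share of ribosomal RNA that was kept is a candidate explanation, and it remains open whether the high or the low groups depart, since no biological explanation was tested.

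Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. As many genes as in the real split came from 1 split, the real one, in each of the 7 comparisons. Every other split mixes both compared groups, so their difference enters the spread and few genes can be called. The counts of other splits, also for genes gained and lost, therefore do not show what chance gives without a difference. The real split gave 5166 genes against 1 in the highest other split for untreated biliary cells and hepatocytes, 2707 against 243 for reprogrammed cells and DDC hepatocytes, and 490 against 39 for reprogrammed and DDC biliary cells. It gave 1529 against 64 for DDC in hepatocytes and 1455 against 2 for DDC in biliary cells. It gave 4590 against 1 for reprogrammed cells and untreated hepatocytes, and 4813 against 1 for DDC biliary cells and DDC hepatocytes. Biliary genes gained were 1590 against 48 and hepatocyte genes lost 763 against 76. In the first 3 comparisons, where the numbers pair the libraries, the 3 other splits that part all pairs gave at most 2 genes, and the 6 that part fewer gave at most 1, 243 and 39. Gene lists called by camera were 24 in the real split against 27 in the highest other, 26 against 22, 21 against 24, 19 against 17, 20 against 21, 25 against 26 and 23 against 27 in the order of the comparisons above. Of the splits, 6, 1, 4, 1, 2, 4 and 6 gave as many. For the overlap of the DDC responses, 1 of 100 drawn splits gave as many shared genes, the real one, with 527 against 1. These splits part the cell types independently and break up the DDC response of each, so few genes could be shared. They tie the overlap to the DDC responses, but cannot tell whether the responses share more genes than by chance. With both cell types split alike by number, which keeps same-numbered libraries together, 10 splits gave 527 against 1, too few for a share under 0.05. For genes beyond both other DDC groups, 10 of 100 gave as many, with 8 against 1255 for higher and 3 against 2179 for lower genes, so chance was not excluded. The large counts in other splits point to the structure of the 3 groups.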

How the results depend on the processing

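The alternatives without Lars2 and the structural and small RNA genes, and without genes higher in untreated hepatocytes, were chosen only after the results were seen.

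Of the values for named genes under the alternatives, 16119 kept their direction and side of the threshold, 1009 fell short of it, 63 passed it, 44 moved and 3 reversed. For lists 2783 kept them, 273 fell short and 2 reversed. Reversed were the stellate and fibroblast list in reprogrammed cells against untreated hepatocytes (0.46) and Cdkn1a between untreated cell types (0.0826) in TPM as deposited, and under quantile normalization the NRF2 list in reprogrammed cells against DDC hepatocytes (0.0113), B2m in reprogrammed cells against untreated hepatocytes (0.37) and Gapdh between DDC cell types (0.032), none of them called by limma or camera then.

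TPM as deposited gave 7820 genes for untreated biliary cells and hepatocytes, 4249 for reprogrammed cells and DDC hepatocytes, 7787 for DDC biliary cells and DDC hepatocytes, 3844 biliary genes gained, 1 hepatocyte gene lost and a hepatocyte gene position of 39.95%. It leaves in the shift of the median gene. In each alternative the biliary and hepatocyte genes behind the gained and lost counts and the positions were defined anew. A pseudocount of 0.1 gave 2330 genes for DDC in hepatocytes, 2412 biliary genes gained, 4 genes higher than in both other DDC groups and an overlap of 807. A pseudocount of 5, which shrinks differences of low genes, gave in the order of comparisons 3367, 1473, 296, 797, 751, 2756, 3012 and 579 for the interaction, with 707 gained, 3 higher than both and an overlap of 295. A filter of 5 TPM gave 5 higher than both. Only the compared groups in the fit gave 3 genes for reprogrammed and DDC biliary cells, and 0 genes higher and 0 lower than both by limma (8 and 6 at unadjusted p under 0.05). Sample weights gave 804, 17 and 12 for the same. The fit of only the compared groups had fewer libraries for the spread. It also left out the untreated libraries, whose replicates correlated more closely than those of the DDC groups. Which of these lowered the counts was not tested. The adjusted p alone gave 9296, 6613, 2060, 3895, 3640, 8794, 9113 and 1777, with 3297 gained, 2637 lost and an overlap of 1501. With an estimated correlation 0 of the 163 list calls held by camera (44 at unadjusted p under 0.05), where fry called 33, 32, 22, 22, 18, 34, 35 and 5 lists. Without Lars2 and the structural and small RNA genes 0 genes were lower than both by limma (1 at unadjusted p under 0.05), since those 3 were among the genes left out, and without genes higher in untreated hepatocytes the overlap was 270. Where no construction is named, the cause was not tested.

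Leaving out 1 library gave 4974 to 5261 genes for untreated biliary cells and hepatocytes, 2237 to 3290 for reprogrammed cells and DDC hepatocytes, 1369 to 1652 and 1190 to 1653 for DDC in hepatocytes and biliary cells. It gave 4324 to 4889, 4498 to 5136 and 932 to 1253 for the last 3. It also gave 1434 to 1783 biliary genes gained, 158 to 168 lists, an overlap of 439 to 560 and positions of 71.86% to 83.75% and 50.36% to 65.93%. Reprogrammed and DDC biliary cells gave 102 to 833 genes, with 833 without reprogrammed library 1, 137 without reprogrammed library 2 and 102 without DDC biliary library 3. Hepatocyte genes lost ran from 497, without reprogrammed library 1, to 1007. Genes higher than both ran from 3 to 11, with 5 without reprogrammed library 1, 3 without reprogrammed library 3, 4 without DDC biliary library 1, 4 without DDC biliary library 2 and 3 without DDC biliary library 3, and genes lower than both from 2 to 3.

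The replicate block over all samples gave 562 genes for reprogrammed and DDC biliary cells against 490 in the main test, and the replicate block within treatment 688. It moved no count of calls by over 1.5 times. Over all samples 981 named genes kept their call, 1 passed and 2 fell short, and within treatment 549 kept it and 1 passed. The unknown depth left the counting error of low values unmeasured.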

Other observations

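The tests of male-predominant and female-predominant liver genes were chosen only after the falls of the Mup family, Elovl3, Hsd3b5, Slco1a1, Cyp4a12a and Cyp7b1 were seen.

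Beside the Mup family, other liver genes that are expressed mainly in male mice fell in DDC hepatocytes. Elovl3, a fatty acid elongase gene, went from 1093 to 0.656 scaled TPM (log2 difference -9.34), Hsd3b5, a steroid dehydrogenase gene, from 350.5 to 0.133 (-8.27) and Slco1a1 from 439 to 0.143 (-8.59). Of 28 measured male-predominant genes, 24 were lower in DDC hepatocytes (median log2 difference -6.92, camera p = 6.81e-28, and p = 0.00314 with an estimated correlation). In DDC biliary cells 23 were lower (-5.45, camera p = 2.31e-22, and p = 0.00642 with an estimated correlation), and 28 in reprogrammed cells against untreated hepatocytes (-7.67, camera p = 3.86e-17, and p = 0.0141 with an estimated correlation). These values include 12 Mup genes and the 5 others that prompted the list. Without the Mup genes, 13 of 16 were lower in DDC hepatocytes (-3.39, camera p = 2.68e-14, and p = 0.00569 with an estimated correlation). Without the 5 others as well, 8 of 11 were lower (-2.48, camera p = 1.38e-07, and p = 0.0131 with an estimated correlation), 7 of 11 in DDC biliary cells (-1.60, camera p = 2.75e-05, and p = 0.0375 with an estimated correlation) and 11 of 11 in reprogrammed cells (-3.30, camera p = 2.1e-06, and p = 0.0219 with an estimated correlation).

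A shift from the male to the female pattern of liver genes is a candidate explanation. Of 26 measured female-predominant genes, 10 were higher in DDC hepatocytes, or 38.5%, and 1 was lower, Lifr, chosen after its value was seen (camera p = 0.00231, and p = 0.254 with an estimated correlation). In DDC biliary cells against untreated biliary cells 1 was higher and 3 were lower (median log2 difference -0.04, camera p = 0.576, and p = 0.829 with an estimated correlation), and in reprogrammed cells against untreated hepatocytes 6 were higher and 4 lower (0.47, camera p = 0.964, and p = 0.986 with an estimated correlation). These comparisons gave no rise of the list by camera, unlike the male-predominant genes, which fell in each. Neither is a separate test of the pattern, since the biliary libraries may hold hepatocyte RNA and the reprogrammed comparison crosses cell types. Between untreated biliary cells and untreated hepatocytes the median log2 difference was -2.56 for male-predominant and -0.923 for female-predominant genes. A general loss of hepatocyte transcripts in reprogrammed cells would therefore lower both lists. In DDC hepatocytes, a loss of male-predominant transcripts alone and a shift of the whole pattern cannot be told apart with a share of 38.5%, and the labels do not give the sex of the mice.

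Not all lists passed in every comparison. In DDC hepatocytes against untreated hepatocytes, the keratin and Mallory-Denk body list had 4 genes higher and 4 lower, with a median of 0.25 and a mean of -0.10, so its summary has no single sign.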
